A study of Homo sapiens and Gallus gallus with 14 samples.

How the data were processed

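PolyA RNA of 14 libraries was sequenced on an Illumina instrument, per the labels: 8 of human 293 cells in 4 groups and 6 of chicken DT40 cells in 3 groups, with 2 libraries per group. Per the submitters' processing notes, reads were aligned with Bowtie to hg19, and no version of Bowtie is given. The notes list hg19 for the chicken libraries as well, while the deposited chicken table carries chicken chromosomes, so the chicken build is not given in the sources used here. Reads were not realigned.

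The values the authors deposited are percent (PSI), the percent of RNA at a place that includes an exon or uses a splice site within a library, and the sources used here do not state how PSI was computed. The alternative sites of 1 event summed to 100 in each library. The deposited quality text, which is of another (other) kind than the percent values, holds a read coverage class per event and library (N, VLOW, LOW, OK or SOK), a read balance class for exons and a pair of read numbers for alternative sites. The second number was taken as the reads at the event. The table leaves its meaning open, and inclusion and exclusion reads of exons are not given, so the depth behind a single exon is known only as a class and no counting interval was computed. Retained introns are not in the tables.

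The human table listed 111869 exons and sites in 15557 genes, of which 15242 identifiers were paired with a symbol by a gene name table. The chicken table listed 97696 in 11354 genes, of which 9969 had a name in the table. For each alternative splice site event the first site was left out, since the sites of an event sum to 100 (17440 human and 31237 chicken sites), with 19 and 5 repeats. Events were tested when they had a PSI in every library of the line, coverage of LOW or better in every library and a mean PSI between 2 and 98. That left 25775 human events and 11234 chicken events (5853 exons, 102 microexons, 2060 alternative 5' sites and 3219 alternative 3' sites).

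PSI was fitted per event with limma 3.58.1 in R 4.3.3 (with the data.table package, version 1.17.8), with lmFit, contrasts.fit and eBayes with trend and robust, over all libraries of a line, so that its groups shared 1 estimate of the spread. The median prior degrees of freedom were 2.81 in 293 and 2.97 in DT40 cells, and the median residual SD was 2.02 and 2.18 points. An event was called at a Benjamini-Hochberg adjusted p under 0.05 over all events of the line and a difference of at least 10 points. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The fit was tested on simulated data with 200 changed events in each line, 100 of 15 points and 100 of 30 points, and with no change, where it called 2 events with full-length PTBP1 against knockdown and 0 in the other comparisons. These are values of a self-test and not measurements.

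The 7 comparisons, the tests, the gene lists, the thresholds and the rule for named genes were chosen before the data were examined. Fisher's exact test compared event types, with Benjamini-Hochberg adjustment over types. The 9 gene lists, drawn from general knowledge, were known PTB targets (25 genes), splicing regulators (72), cytoskeleton and adhesion (68), membrane trafficking (74), neuronal microexon genes (50), transcription and chromatin (79), apoptosis (36), cell cycle and centrosome (55) and B lymphocyte genes (41), and some genes are in more than 1 list. Each was compared with 10000 random lists matched on the number of tested events per gene, 1-sided, with adjustment over lists. The smallest p these can give, adjusted over lists, is 0.000225 where 4 lists share it. Each list was also tested adjusted over the list alone. Chosen after seeing the data were a count of known PTB targets without PTBP1, and random lists adjusted alone in the same way for homozygous against wildtype DT40 cells.

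Named genes are, per comparison, the 8 exons with the largest rise and the 8 with the largest fall among called events whose groups did not overlap, 1 per gene, up to 8 called events of known PTB targets, and the tested exons of PTBP1, PTBP2 and PTBP3. Genes named with a gene list, a microexon, a comparison with control or a DT40 result are outside this rule and were chosen after their values were seen. Some genes that the rule or a list picked are not reported here, while the counts include them. Functions of genes are general knowledge. Reads per 1000000 (RPM) are the reads at an event scaled to 1000000 reads at all alternative sites of a library, and measure no whole transcript.

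Alternatives were the scale log2((PSI + 1) / (101 - PSI)), other coverage, difference and mean PSI filters, eBayes without trend and robust, a fit of the compared groups alone, no test, and each library left out in turn. Chosen after seeing the data were a different knockdown library in each of a pair of comparisons, the use of first sites, balanced exon reads, the deepest coverage class and the comparisons of both PTBP1 forms with control. One library of each human group is numbered 2 and the other is not numbered, and a fit with this number as a block was run for 293. No paired analysis was possible because the DT40 columns carry no replicate numbers that join the groups, which applies to the DT40 comparisons and to the overlap between lines.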

Results

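Splicing was measured by polyA RNA sequencing in human 293 cells (an embryonic kidney line) and in chicken DT40 cells (a B lymphocyte line). The human set held 8 libraries in 4 groups of 2: cells given a control siRNA, cells given siRNAs against PTBP1 and PTBP2, and knockdown cells that also overexpressed PTBP1 either in full length or without its alternative exon. The chicken set held 6 libraries in 3 groups of 2: wildtype cells, cells with PTBP1 exon 8 deleted on 1 allele and cells with it deleted on both. PTBP1 and PTBP2 are polypyrimidine tract binding proteins, which mostly repress exons, and chicken exon 8 is the counterpart of human exon 9. For every exon or splice site and every library the deposited values give the PSI, the percent of RNA that includes the exon or uses the site. Group values below are means with the SD of 2 libraries, differences are in PSI points, and adjusted p-values are from limma; these p-values measure the spread between these libraries.

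The deposited tables give no read total per library. The deepest coverage class was reached by 60.3% and 57.7% of tested events in the control libraries, 70.3% and 71.7% after knockdown, 66.8% and 75.2% with full-length PTBP1 and 64.7% and 72.1% with exon-excluded PTBP1. In DT40 it was reached by 57.9% and 50.1% in wildtype, 58.1% and 48.1% in heterozygous and 55.3% and 45.6% in homozygous cells. Reads counted at alternative splice sites ran from 3766674 to 6255217 per human library and from 9015885 to 11519378 per chicken library. In simulated human data 71 of 100 events changed by 30 points were recovered and 14 of 100 changed by 15 points, with 4 false calls among 25575 unchanged events.

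The targeted genes were examined first. Reads at a PTBP1 splice site pair outside the alternative exon went from 390 ± 19.0 per 1000000 alternative-site reads (RPM) in control to 75.6 ± 5.43 in the libraries labelled double knockdown, which is 0.194 of control. They stood at 1358 ± 169 with full-length and 1153 ± 49.5 with exon-excluded PTBP1. Reads into the alternative exon were 218 ± 20.1 RPM in control, 33.9 ± 7.66 after knockdown, 1087 ± 99.0 with full-length PTBP1 and 28.3 ± 6.88 with exon-excluded PTBP1. PTBP1 exon 9, listed with its 57 nt form (hg19 19:805513-805569), had a PSI of 77.0 ± 0.919% in control, 72.8 ± 3.76% after knockdown, 98.5 ± 0.113% with full-length and 4.14 ± 0.651% with exon-excluded PTBP1, and in the last 2 groups reads of the introduced cDNA can enter the value. PTBP2 reads did not fall: at 1 site pair they were 19.1 ± 2.36 RPM in control and 25.9 ± 4.15 in the libraries labelled double knockdown, and at another 34.3 ± 8.57 and 40.8 ± 8.84. The label of the knockdown is thus checked for PTBP1 RNA and not for PTBP2 RNA, and "knockdown" below means those libraries. In DT40, reads into the acceptors of 1 PTBP1 exon were 609 and 512 in wildtype, 340 and 306 in heterozygous and 1 and 0 in homozygous cells, and those across its donors were 417 and 310, 213 and 156, and 1 and 0. At the other PTBP1 site pairs the heterozygous and homozygous means were between 0.906 and 1.05 of wildtype.

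**Figure D1:**
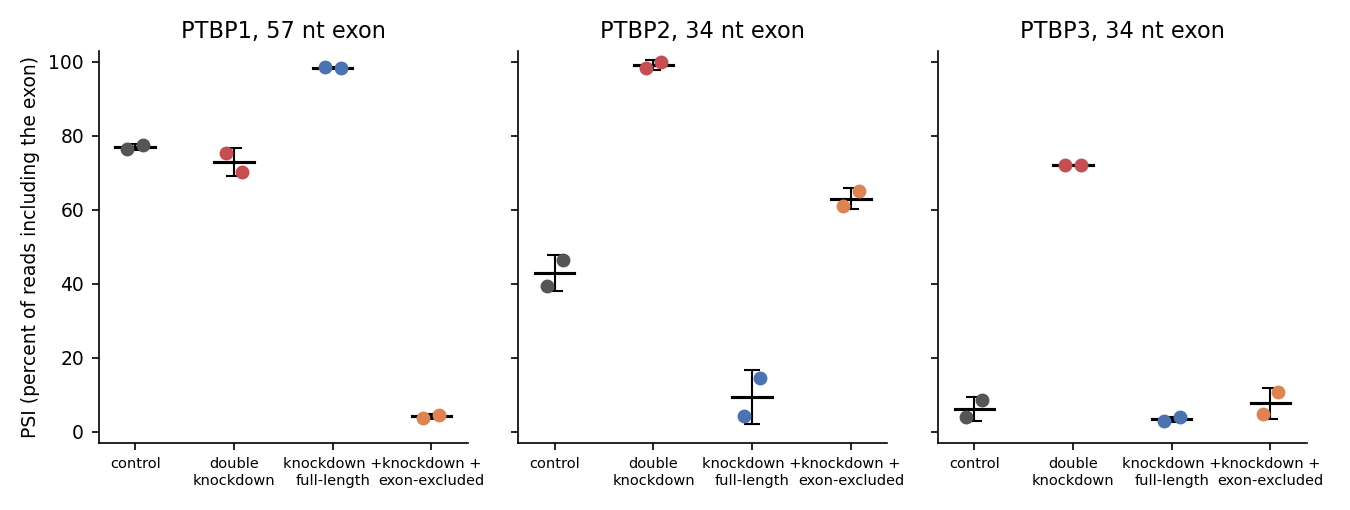
PSI (percent) of the alternative exons of PTBP1, PTBP2 and PTBP3 in the 8 libraries of 293 cells, with points for libraries, bars for group means and error bars for SD. The PTBP2 and PTBP3 exons were at 99.1% and 72.2% after knockdown, and the PTBP2 exon stood at 63.0% with exon-excluded and 9.37% with full-length PTBP1.

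The first comparison asked what siRNAs against PTBP1 and PTBP2 did to splicing in 293 cells. Knockdown changed 1759 of 25775 tested events, in 1318 of 8115 genes. Inclusion or site use was higher for 781 events and lower for 978. The median size of a called change was 19.2 points. Genes of the chosen cytoskeleton and adhesion and membrane trafficking lists stood out, and the microexons among the calls mostly became more included.

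The PTBP family's own exons were among the changes. The 34 nt exon of PTBP2 (1:97271975-97272008), whose skipping shifts the reading frame, rose from 43.0 ± 4.87% to 99.1 ± 1.25% (adjusted p 0.000319). The 34 nt exon of PTBP3 (9:115092721-115092754) rose from 6.19 ± 3.25% to 72.2 ± 0.00707% (adjusted p 1.2e-05). PTBP1 exon 9 differed by −4.19 points, which did not pass (adjusted p 0.457), and neither the 78 nt exon of PTBP2 (96.1% and 99.1%) nor the 170 nt exon of PTBP3 (77.1% and 77.8%) was called.

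The largest rises took exons from near absence to near full use. A 189 nt exon of PHLDB2, which anchors microtubules at the cell cortex, rose from 0.0% to 98.6 ± 2.05% (3:111668549-111668737; SE 2.45, adjusted p 1.71e-06). A 168 nt exon of ITPRID2, an actin-binding partner of inositol trisphosphate receptors, rose from 1.57 ± 0.636% to 95.9 ± 0.318% (2:182781565-182781732; adjusted p 1.5e-06). The deubiquitinase gene USP16 (63 nt, 21:30398030-30398092) rose by 93.7 points and the glucose-6-phosphate transporter gene SLC37A4 (66 nt, 11:118896402-118896467) by 93.0. A 111 nt exon of ATG13, a scaffold of the autophagy initiation complex, went from 0.220% to 92.0% (11:46686399-46686509; adjusted p 2.02e-06). An exon of ABI2 (183 nt, 2:204261508-204261690), part of the WAVE actin-nucleation complex, rose by 90.6 points. LRRFIP2, a flightless-1 binding protein, gained 88.8 points at a 102 nt exon (3:37107715-37107816).

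The largest falls took exons from high to low use. A 126 nt exon of the DNA methyltransferase gene DNMT3B went from 85.4 ± 1.15% to 5.34 ± 0.431% (20:31374308-31374433; SE 3.64, adjusted p 2.54e-05). The mechanosensitive channel gene TMEM63B lost most of a 39 nt exon, from 94.9 ± 1.97% to 16.5 ± 1.77% (6:44103065-44103103). The sodium-proton exchanger gene SLC9A7 went from 89.98% to 11.63% (60 nt, X:46495024-46495083). PACSIN2, which bends membranes at caveolae and endocytic sites, went from 96.1% to 19.8% (123 nt, 22:43272894-43273016; adjusted p 4.6e-06). KIAA1217, an adaptor linked to skeletal development, fell by 76.2 points (120 nt, 10:24825703-24825822), and the SNARE gene STX3, which encodes an apical syntaxin, by 75.3 (114 nt, 11:59564756-59564869). SH3PXD2A, a scaffold of invadopodia, fell by 74.0 points (84 nt, 10:105382227-105382310).

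Known targets of PTB gave some of the clearest changes. In TPM1, which encodes the actin-filament protein tropomyosin, a pair of neighbouring 76 nt exons traded places: 1 rose from 5.80 ± 1.20% to 92.9 ± 0.149% (15:63353912-63353987; adjusted p 3.64e-06) and the other went from 96.8 ± 1.37% to 25.0 ± 1.49% (15:63353397-63353472). A 79 nt TPM1 exon rose from 4.55% to 74.8% (15:63356263-63356341). TPM2 lost a 76 nt exon, from 73.9 ± 1.31% to 7.61 ± 0.240% (9:35685061-35685136; adjusted p 0.000103). A 12 nt microexon of AGRN, which encodes the proteoglycan agrin, rose from 5.80 ± 0.0141% to 92.5 ± 2.00% (1:986412-986423; adjusted p 1.5e-06). The 2400 nt exon of the endoplasmic reticulum gene RTN4 rose from 2.55% to 74.8% (2:55252222-55254621). In each comparison the naming rule picks the largest changes and known targets, so their stability says little of the other calls. All 24 changes that the naming rule picked were called again when any single library was left out, while the total became 1156 without control replicate 2, the only library whose absence moved it by more than 1.5 times. The balance of directions depended on the setting. Higher events outnumbered lower ones without a coverage filter (799 and 605) and with the compared groups alone (548 and 450). They also did so without either control library or the unnumbered knockdown library. Lower events outnumbered higher ones more strongly in the deepest coverage class (393 higher and 718 lower) and with balanced exon reads (361 and 660).

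Exon types responded unequally. Of 331 microexons (27 nt or less) 100 were called, 30.2% (Fisher exact odds ratio 6.21, adjusted p 8.64e-38), and 85 of these were higher. Longer exons were called at 7.37%, 1557 of 21134, with 631 higher and 926 lower. Alternative 5' sites (49 of 1948) and alternative 3' sites (53 of 2362) were called less often, with odds ratios of 0.334 and 0.292. Microexons that rose included those of CTNND1, the p120 catenin of adherens junctions (18 nt, 2.57% to 90.8%), PDLIM5, a Z-disc and actin adaptor (18 nt, from 3.88%), the focal adhesion kinase gene PTK2 (9 nt, 10.0% to 68.5%), the microtubule plus-end genes CLIP1 (6 nt, 3.65% to 75.3%) and CLASP1 (24 nt, 32.2% to 83.4%), and the clathrin adaptor gene AP1B1 (21 nt, 0.375% to 68.1%). A 3 nt exon of CLASP2 went the other way, from 87.8% to 44.8%. Without control replicate 2, 4.59% of exons and 1.41% of alternative 5' sites were called, and without the unnumbered knockdown library 1.496% of alternative 5' sites were.

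**Figure D2:**
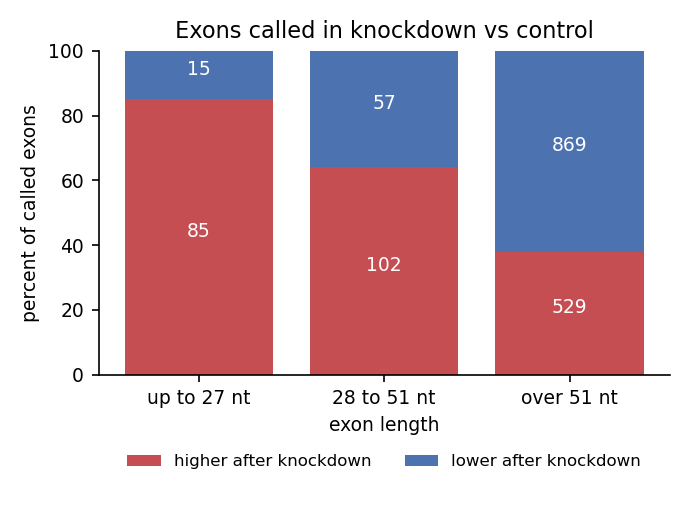
Percent of exons called in knockdown against control that were higher or lower after knockdown, by exon length in nt, with the number of exons printed in each part of a bar. Of the exons up to 27 nt 85 were higher and 15 lower, and of those from 28 to 51 nt 102 were higher and 57 lower.

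Gene lists fixed in advance were set against random lists. The lists were picked from general knowledge, and some share genes with the known PTB targets. Random lists were matched only on the number of tested events per gene, so an effect of how the genes were picked stays open. Of the known PTB targets 15 of 19 tested genes had a called event, against 3.37 in random lists, and 15 when adjusted over the list alone. The cytoskeleton and adhesion list had 43 of 59 (random 15.3, adjusted over the list alone 45), membrane trafficking 41 of 67 (15.8, 43 over the list alone) and the neuronal microexon genes 28 of 43 (11.7, 28 over the list alone), each with adjusted p 0.000225. Besides the genes above these held SVIL, a membrane-actin linker (96 nt, 3.78% to 90.1%), the kinesin gene KIF21A (39 nt, 11.3% to 94.3%), the actin crosslinker gene ACTN4 (86 nt, 4.15% to 76.2%), the endocytic scaffold gene ITSN2 (81 nt, 0.0% to 80.4%), DNM1 of vesicle scission (37 nt, 15.8% to 81.9%), and the active-zone gene ERC1 (84 nt, 65.8% to 8.96%). Transcription and chromatin genes had 28 of 76 (random 18.6, adjusted p 0.0117, 30 over the list alone), among them HDAC7 (258 nt, 3.45% to 73.5%), TCF12 (72 nt, 8.41% to 67.4%), DNMT3A (100% to 65.6%) and the Polycomb gene EZH2 (85.5% to 59.5%).

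The remaining lists were not enriched. Splicing regulators had 11 of 65 called (random 12.02, p 0.685, 10 adjusted over the list alone), with CELF1 (105 nt, 45.1% to 5.41%), MBNL2 (36 nt, 1.74% to 29.7%) and HNRNPM (45 nt, 96.6% to 68.8%) among them. Cell cycle and centrosome genes had 17 of 48 (random 11.8, p 0.0538, 17 over the list alone), led by the centriolar satellite gene PCM1 (184 nt, 2.61% to 79.2%), and 10 without control replicate 2 or 9 without the unnumbered knockdown library. Apoptosis genes had 5 of 27 (random 4.23, p 0.424, 5 over the list alone), including CASP2 (61 nt, 7.35% to 31.2%), and 2 without control replicate 2 or 3 without either knockdown library. B lymphocyte genes had 3 of 9 (p 0.0405 before adjustment over lists, 3 over the list alone), among them the kinase gene SYK (69 nt, 67.0% to 43.5%), and 1 without knockdown replicate 2.

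The next comparison asked what returning full-length PTBP1 did to knockdown cells. It changed 2199 events in 1628 genes, 1030 higher and 1169 lower. Without the unnumbered full-length library these were 605 and 913, without the second 684 and 970, and without the unnumbered and second knockdown library 731 and 918 and 781 and 905. Most changes undid the knockdown: 686 of the 781 events that had risen (87.8%) were called back down and 678 of the 978 that had fallen (69.3%) were called back up. Independent lists of these sizes would share 35.4 and 39.1, though 1 estimate of the spread for all groups favours common calls. Both comparisons use the same knockdown libraries, so each was also run with a different one, a test chosen after seeing the data: 515 of 622 and 522 of 615 events that had risen were called back, and 398 of 619 and 388 of 671 that had fallen. Of the events changed by the knockdown, 0 that had risen and 3 that had fallen moved further the same way.

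Full-length PTBP1 returned skipped exons to high use. DNMT3B rose by 86.6 points to 91.9 ± 2.15% (adjusted p 1.55e-05), KIAA1217 by 85.5 to 100%, STX3 by 80.4 and SLC9A7 by 78.7. The ubiquitin ligase gene NEDD4L, which limits sodium channels at the membrane, rose from 18.8 ± 2.62% to 92.2 ± 2.33% at a 120 nt exon (18:56008910-56009029; adjusted p 7.83e-06). SERP2, of the endoplasmic reticulum stress response, rose from 4.995 ± 2.37% to 78.2 ± 4.72% at a 222 nt exon (13:44964493-44964714; adjusted p 7.85e-05). The TPM1 exon lost after knockdown regained 73.1 points and PACSIN2 72.8. PTBP1 exon 9, not called after knockdown, was 25.7 points higher (adjusted p 0.00148), a value that includes the introduced cDNA, which holds it.

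The same PTBP1 form silenced the exons that knockdown had released. PHLDB2 changed by −97.9 points to 0.615 ± 0.870% (adjusted p 1.71e-06), ITPRID2 by −92.6, SLC37A4 by −92.1 and USP16 by −91.4. A 24 nt microexon of NAV1, a neuron navigator that guides migrating neurons, went from 96.7 ± 2.09% to 4.11 ± 5.81% (1:201759682-201759705; adjusted p 1.55e-05). A 15 nt microexon of PLEC, which encodes the cytoskeletal linker plectin, went from 90.6 ± 6.04% to 0.0% (8:145012569-145012583; adjusted p 1.26e-05), and P3H3, a collagen prolyl hydroxylase gene, from 93.6 ± 0.870% to 3.11 ± 1.26% (164 nt, 12:6940034-6940197). Among known targets PTBP2 changed by −89.8 points, AGRN by −86.9, DLG4, a postsynaptic scaffold, by −71.4 (110 nt, 17:7095212-7095321), RTN4 by −70.2 and PTBP3 by −68.8. All 24 changes that the naming rule picked were called again without any single library.

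Microexons again stood out, with 120 called, 16 higher and 104 lower (Fisher exact odds ratio 6.39, adjusted p 1.26e-44), beside 973 longer exons higher and 985 lower. Known PTB targets (16 genes called, 16 adjusted over the list alone, and 15 and 15 without PTBP1 itself), cytoskeleton and adhesion (43, 45 over the list alone), membrane trafficking (41 and 41), neuronal microexon genes (33 and 33, each of the 4 lists with adjusted p 0.000225) and transcription and chromatin (32 and 32, adjusted p 0.0146) were enriched. Splicing regulators (10 and 10), apoptosis (7 and 7), cell cycle and centrosome (18 and 19) and B lymphocyte genes (3 and 3) were not.

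PTBP1 without its alternative exon was compared with the same knockdown cells. It changed 1398 events in 1101 genes, 591 higher and 807 lower. It called back 600 of the 781 events that had risen (76.8%) and 475 of the 978 that had fallen (48.6%). Independent lists would share 24.5 and 22.4, with the same limit. With a different knockdown library in each comparison 456 of 622 and 458 of 615 events that had risen were called back, and 238 of 619 and 243 of 671 that had fallen, again chosen after seeing the data. The total was 781 without the unnumbered exon-excluded library, and leaving out any other library moved it by less than 1.5 times. Higher calls moved more: 263 and 339 were left without the unnumbered and second exon-excluded library, 353 and 359 without either knockdown library, 313 with the compared groups alone and 363 on the logit scale.

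The largest falls were at exons that the long form also silenced. PHLDB2 changed by −87.6 points, PLEC by −87.4 to 3.16 ± 4.46%, SLC37A4 by −80.2 and ITPRID2 by −80.0. A 21 nt microexon of the dynactin gene DCTN1, which serves dynein transport, went from 90.03 ± 1.54% to 8.59 ± 3.90% (2:74600055-74600075; adjusted p 6.8e-06). A 33 nt exon of the integrin activator FERMT2 went from 84.9 ± 0.516% to 3.84 ± 1.19% (14:53348514-53348546; adjusted p 3.1e-06). ANXA7, a calcium-dependent membrane fusion gene, went from 82.5 ± 1.82% to 3.18 ± 0.905% (66 nt, 10:75155802-75155867), and the fibrillin gene FBN1 from 88.6 ± 3.19% to 9.35 ± 1.55% (62 nt, 15:48720079-48720140). AGRN changed by −72.0 points, the 76 nt TPM1 exon by −70.7, PTBP3 by −64.5, DLG4 by −61.6 and RTN4 by −59.0. PTBP2 changed by −36.2 (adjusted p 0.00343) and stayed at 63.0%. PTBP1 exon 9 changed by −68.7, a value set by the introduced cDNA that lacks it.

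Exons that rose again did so by up to 63.0 points. That largest rise was in TPM1, followed by NEDD4L with 62.6. The receptor phosphatase gene PTPRF, which acts in adhesion, rose from 32.1 ± 1.34% to 90.2 ± 1.51% at a 579 nt exon (1:44069282-44069860; adjusted p 1.4e-05), and PACSIN2 rose by 58.1. MYO5C, an unconventional myosin of secretory granules, rose by 54.1 (99 nt, 15:52505385-52505483), SYNRG, a clathrin adaptor partner, by 53.8 (167 nt, 17:35937545-35937711) and STX3 by 53.7.

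Microexons called with exon-excluded PTBP1 numbered 89, 9 higher and 80 lower (Fisher exact odds ratio 6.78, adjusted p 5.02e-37), beside 554 longer exons higher and 671 lower. Known PTB targets (13 genes called, 14 adjusted over the list alone, and 12 and 13 without PTBP1 itself), cytoskeleton and adhesion (40 and 41), membrane trafficking (34 and 39) and neuronal microexon genes (25 and 27) were enriched, each with adjusted p 0.000225. Transcription and chromatin (20 and 20), cell cycle and centrosome (15 and 16), splicing regulators (7 and 6), apoptosis (5 and 5) and B lymphocyte genes (2 and 3) were not.

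The direct comparison of the PTBP1 forms asked what the alternative exon adds. Cells with exon-excluded PTBP1 differed from cells with full-length PTBP1 at 158 events in 139 genes, 96 higher and 62 lower, a balance that turned in several settings given below. Of these 124 were also called in the knockdown, and 123 of the 124 leaned toward the knockdown state, and no library is in both comparisons. All groups share 1 estimate of the spread, which favours common calls but not a common direction. The median size was 22.9 points.

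Most of the largest differences were at exons released by the knockdown. Some of these stayed partly released under the short form, and at some full-length PTBP1 went below control. The PTBP2 34 nt exon was at 63.0 ± 2.80% with exon-excluded and 9.37 ± 7.32% with full-length PTBP1 (difference 53.6, adjusted p 0.00818). Its control value of 43.0 ± 4.87% lay between them. A 96 nt exon of ARHGEF11 was at 81.9% in control, 82.1% with exon-excluded and 40.2% with full-length PTBP1. The PTBP3 exon was repressed under both forms, at 7.68 ± 4.14% and 3.32 ± 0.764% (adjusted p 0.602). A 141 nt exon of AKAP9, which anchors protein kinase A at the Golgi and centrosome, was at 65.4 ± 0.601% and 19.4 ± 3.28% (7:91671360-91671500; adjusted p 0.0135). A 9 nt microexon of the kinase gene MAP4K4 was at 59.0 ± 3.83% and 14.8 ± 1.00% (2:102484491-102484499; adjusted p 0.00977). SUCO, of rough endoplasmic reticulum and bone matrix secretion, was not called in the knockdown (21 nt, 1:172546679-172546699). This exon stood at 93.9% in control and 100% after knockdown, so it had too little room to rise to be called. It was at 93.4 ± 1.97% with exon-excluded and 53.5 ± 3.44% with full-length PTBP1 (adjusted p 0.0054). SNAP91, a synaptic clathrin assembly gene, was higher by 38.6 points (6:84265862-84265964), the stress kinase gene MAP3K4 by 37.5 (150 nt, 6:161519310-161519459) and a 21 nt microexon of FERMT2 by 37.0 (14:53327732-53327752). Among PTB targets the 76 nt exon of TPM1 was higher by 18.5 (adjusted p 0.0437) and AGRN by 14.9 (adjusted p 0.0387).

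Exons lost in the knockdown were restored less by the short form. Apart from PTBP1 exon 9 itself, which the introduced cDNAs set (difference −94.3, SE 2.85, adjusted p 0.000169), ZNF711, an X-linked zinc finger gene, was at 36.0 ± 2.16% with exon-excluded and 81.1 ± 3.39% with full-length PTBP1 (143 nt, X:84501936-84502078; adjusted p 0.0188). SERP2 differed by −42.5 points (adjusted p 0.017), and FAM135A, a gene of unsettled function, by −41.0 (78 nt, 6:71195870-71195947). COBL, an actin nucleator of neurons, differed by −36.3 (171 nt, 7:51150755-51150925; adjusted p 0.0306), DNMT3B by −33.2, the kinase anchor gene AKAP11 by −32.3 (84 nt, 13:42887183-42887266) and TPM2 by −26.5 (adjusted p 0.049).

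This set of calls was sensitive to single libraries. The count was 81 and 71 without the unnumbered and second control library, 30 and 30 without either knockdown library, 15 and 35 without either full-length library, and 9 and 8 without either exon-excluded library. Lower events outnumbered higher ones without either control library (36 higher and 45 lower, 33 and 38), full-length library (6 and 9, 16 and 19) or exon-excluded library (1 and 8, 1 and 7), without a coverage filter (59 and 82) and with the replicate number as a block (25 and 35). Of the 19 events that the naming rule picked 14 were called without either control library, with AGRN, COBL, DNMT3B, TPM1 and TPM2 lost, and 8 without either knockdown library. Without the unnumbered full-length library 4 were called, without the second 8, without the unnumbered exon-excluded library 2 (PTBP1 among them) and without the second 1 (PTBP1).

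Of the microexons 20 were called, 17 higher and 3 lower (Fisher exact odds ratio 11.8, adjusted p 7.44e-14), beside 77 longer exons higher and 57 lower, 1 alternative 5' site and 3 alternative 3' sites. Without PTBP1, whose exon the cDNAs set, known PTB targets had 4 of 18 genes called and 6 adjusted over the list alone (random 0.338, adjusted p 0.0012, chosen after seeing the data), and 5 and 7 with it. Cytoskeleton and adhesion (12, 25 over the list alone, adjusted p 0.00045) and membrane trafficking (8 and 16, adjusted p 0.0012) were enriched as well. These enrichments rest on the full set of libraries, as counted after seeing the data: without the unnumbered and second exon-excluded library 0 and 1 microexons, 2 and 1 cytoskeletal and 0 and 0 membrane trafficking genes were called, without either full-length library 3 and 3, 1 and 2 and 0 and 1, and with the compared groups alone 0, 0 and 0. Without a coverage filter 4 microexons were called (Fisher exact p 0.119), and 2 known PTB targets. With the compared groups alone the 1 known PTB target called was PTBP1. Cytoskeletal members higher with the short form included ABI2, ACTN4, CLIP1, CTNND1, KIF21A, LRRFIP2, SPTAN1 and TPM1, and those lower included DST and TPM2. Neuronal microexon genes (4 and 10, with AGRN, PTK2 and PTPRS higher and ERC1 lower), transcription and chromatin (4 and 7, with BRD8, DNMT3B, HDAC6 and SMARCA1 lower) and cell cycle and centrosome (3 and 3) were not past the threshold over lists. Splicing regulators (0 and 0), apoptosis (0 and 0) and B lymphocyte genes (0 and 1) had no limma call over all events, of which 2920 had an unadjusted p under 0.05.

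All exons of the knockdown set were then followed as a group, whether or not the forms differed at each. Over the 716 exons higher after knockdown (605 genes) mean PSI was 22.0 ± 0.00633% in control, 54.5 ± 0.348% after knockdown, 19.4 ± 0.230% with full-length and 26.7 ± 0.845% with exon-excluded PTBP1. The forms differed by 7.28 points (pooled SD 0.619; median 4.545 per exon), and 87.0% of the exons were higher with the short form. The long form recovered 108% of the knockdown change and the short form 85.6%. For the 85 microexons alone the means were 17.5, 55.4, 13.5 and 23.7%, a difference of 10.2 points. Over the 941 exons lower after knockdown (731 genes) the means were 77.9, 56.6, 76.1 and 70.8%, a difference of −5.26 points (pooled SD 0.442; median −3.71 per exon), with recoveries of 91.5% and 66.8%. Control libraries helped choose the exons, which favours a control mean far from the knockdown. Against a control library left out of the choice, full-length PTBP1 lay at 0.0963 and −0.615 points for exons lower after knockdown. For exons higher it lay at −3.05 and −2.70 points. The 91.5% therefore need not be a shortfall of the long form. For both sets the exact two-sided permutation p was 0.33, the smallest that 2 libraries against 2 can give.

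**Figure D3:**
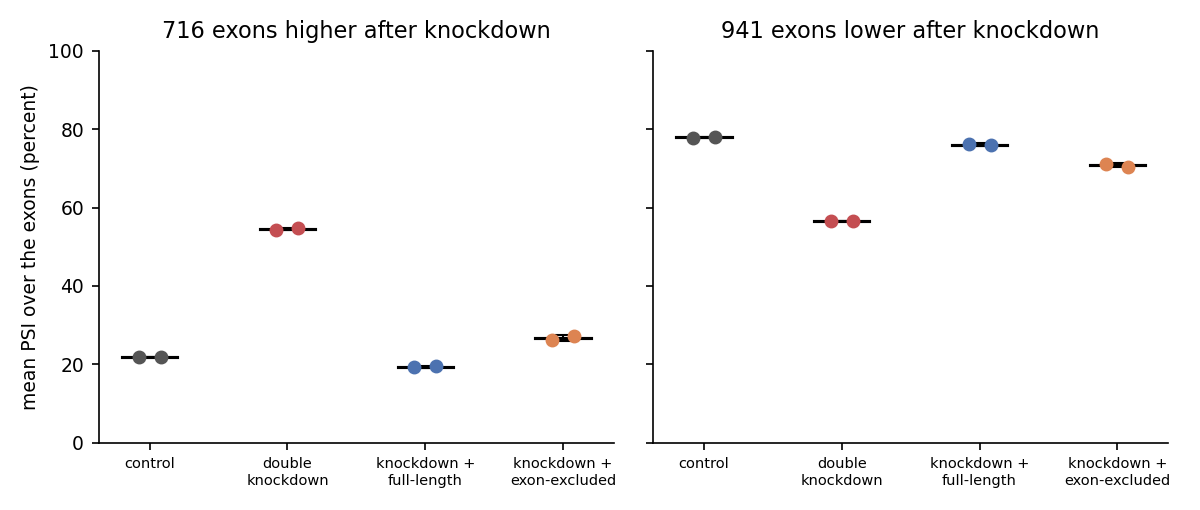
Mean PSI (percent) over the 716 exons higher and the 941 exons lower after knockdown in each 293 library, with points for libraries, bars for group means and error bars for SD. In both sets the exon-excluded libraries lay between the knockdown and the full-length libraries, at 26.7% and 70.8%.

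The chicken comparisons asked what deleting the PTBP1 exon from its own locus did in DT40 cells. Of 11234 tested events in 4426 genes limma called 0 in homozygous against wildtype, in heterozygous against wildtype and in homozygous against heterozygous cells. The smallest adjusted p-values were 0.373, 0.888 and 0.774. At an unadjusted p under 0.05 there were 755, 593 and 655 events, where chance gives 562. In simulated DT40 data 75 of 100 changes of 30 points were recovered and 7 of 100 of 15 points, so most changes of 15 points would be missed with these libraries.

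Genes of the cytoskeleton and adhesion list passed more often than random lists when adjusted over the list alone, with the same limit on how genes were picked. In the cytoskeleton and adhesion list, fixed in advance, 7 of 32 tested genes passed in homozygous against wildtype cells when adjusted over the list alone and 0 over all events. Random lists treated alike had a mean of 0.124 and at most 4 such genes (p 0.0001, the smallest that 10000 lists can give, adjusted p 0.0009), a test chosen after seeing the data. They included TPM1, TPM3, EPB41, MAP2, MACF1 and MYO5A (coordinates are of the chicken table, whose build is not given in the sources used here). A 76 nt TPM1 exon was at 9.65 ± 1.69% in wildtype, 14.6 ± 3.49% in heterozygous and 36.5 ± 5.59% in homozygous cells (10:5116572-5116647; limma p adjusted over this list 0.00705). Its 76 nt neighbour stood at 90.7 ± 3.23, 87.3 ± 4.21 and 65.8 ± 1.21% (10:5117132-5117207). The values of these TPM1 exons came closer, while those of a pair of TPM3 exons moved apart. Of the TPM3 exons 1 went from 28.2 ± 0.735 over 21.0 ± 1.02 to 12.6 ± 1.05% (25:1451614-1451689) and the other from 66.8 ± 0.651 over 75.5 ± 0.827 to 85.6 ± 2.17% (25:1451049-1451124). EPB41, of the membrane skeleton, was at 53.3 ± 1.82, 43.8 ± 0.735 and 28.7 ± 0.276% (117 nt, 23:2941224-2941340), and the microtubule protein gene MAP2 at 58.2 ± 2.09, 48.1 ± 1.43 and 33.6 ± 2.18% (93 nt, 7:2535762-2535854). MACF1, a linker of microtubules and actin, was at 65.8, 71.9 and 80.4% (111 nt), and the myosin gene MYO5A at 46.5, 22.7 and 16.2% (81 nt).

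The other lists gave little. Known PTB targets had 1 of 9 genes adjusted over the list alone (TPM1; random 0.0665, p 0.0612) in homozygous against wildtype and 1 in homozygous against heterozygous cells. In the latter comparison the cytoskeleton list had 1 (TPM1) and membrane trafficking 1 of 52 (DENND1A, an endocytic Rab activator, 100% to 86.7%). All other lists had 0 adjusted over the list alone in the 3 comparisons: splicing regulators (38 genes), neuronal microexon genes (22), transcription and chromatin (40), apoptosis (15), cell cycle and centrosome (32) and B lymphocyte genes (24). Over all events every list had 0 limma calls in the 3 comparisons, with 755, 593 and 655 events at an unadjusted p under 0.05.

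When only the 4855 events in the deepest coverage class were fitted, 10 were called in homozygous against wildtype cells, 5 higher and 5 lower, though their adjusted p-values over all events were 0.373 to 0.519. Besides TPM1, TPM3, EPB41 and MAP2 they were a 24 nt microexon of THOC1, an mRNA export gene (56.0 ± 1.15, 45.8 ± 5.99 and 25.4 ± 1.88%; 2:105290181-105290204), an 84 nt exon of ATG13 (8.79 ± 0.559, 11.9 ± 0.495 and 22.5 ± 1.95%; 5:25639989-25640072), a 99 nt exon of R3HDM1, which encodes an R3H domain protein (11.97, 16.24 and 25.74%; 7:32223845-32223943), and a 60 nt exon of a gene without a name in the table (22.9, 31.1 and 42.0%). The heterozygous mean lay between the other means at each of these exons. They were chosen for the difference between those other groups, which favours a middle value, so this order is no separate support. This setting was chosen after seeing the data. PTBP1's 34 nt exon (28:2308655-2308688) was at 93.4% in wildtype and 86.3% in homozygous cells, a difference of −7.12 points that did not pass (adjusted p 0.664), and the 34 nt exon of PTBP2 (8:13645107-13645140) differed by 0.680 (adjusted p 0.992).

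**Figure D4:**
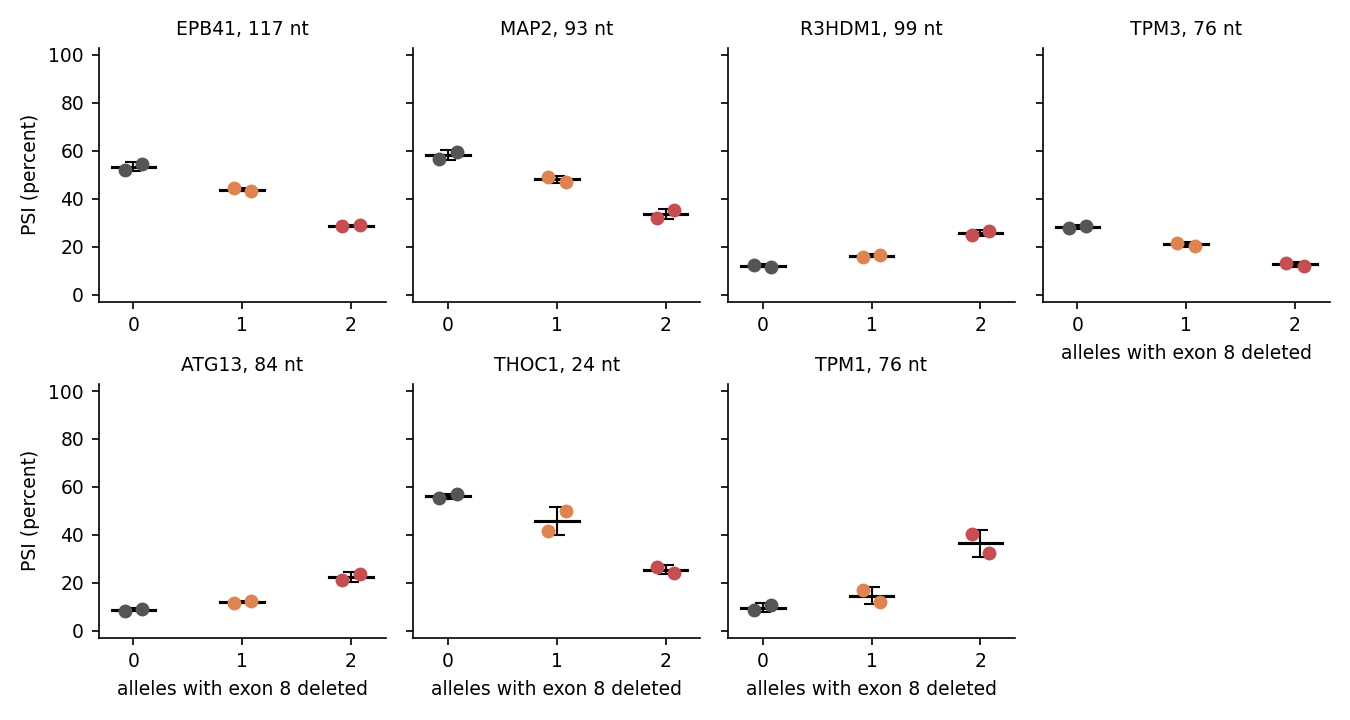
PSI (percent) of 7 chicken exons against the number of alleles with PTBP1 exon 8 deleted, with points for libraries, bars for group means and error bars for SD. These exons were chosen from the 10 called in the deepest coverage class, and TPM1 went from 9.65% to 36.5%.

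The last comparison set the lines side by side. Among 1992 genes with a tested exon in both, 404 were called in the human knockdown and 0 in homozygous DT40 cells by limma, so 0 were shared (Fisher exact p 1.0), with 755 DT40 events at an unadjusted p under 0.05. In the deepest coverage class 993 genes were tested, 183 and 5 were called and 3 were shared (Fisher exact p 0.0461). Exons were also matched by gene symbol and length, which gave 794 pairs. Of 57 whose human exon was higher after knockdown 34 were higher in homozygous than wildtype DT40 cells, with a mean difference of 1.83 points and a median of 0.68. Of 56 that were lower 23 were, with a mean of −1.04 and a median of −0.78. Of the other 681 pairs 53.7% were higher. In TPM1 1 of a pair of 76 nt exons was higher and the other lower in each line, and in DT40 these differences passed adjusted over the list alone and in the deepest coverage class, not over all events.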

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

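The tests of read depth and amount of PTBP1 RNA for the difference between the PTBP1 forms, and of other orders of the DT40 libraries, were chosen only after the result was seen.

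Reads at alternative splice sites of the PTBP genes were not part of the splicing comparisons, and some lay above the control level. In 293 cells PTBP2 reads in the libraries labelled double knockdown were 1.36 of control at 1 site pair, and PTBP3 reads with full-length PTBP1 were 1.14 of control. PTBP2 reads at that site pair were 0.560 of control with full-length and 0.9265 with exon-excluded PTBP1, and 0.488 and 0.761 at the other. In DT40 cells PTBP1 reads at 1 site pair in heterozygous cells were 1.05 of wildtype. Chicken PTBP2 reads in heterozygous cells were 1.23, 1.44 and 1.54 of wildtype at 3 site pairs and 0.978 at another, and in homozygous cells 1.53, 1.59, 1.4 and 1.95 at 4. The PTBP2 counts per library are low, groups hold 2 libraries and no test of gene level was made.

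The first pattern is that exons sat nearer the knockdown state with exon-excluded than with full-length PTBP1. For exons higher after knockdown read depth is argued against, since their difference in the deepest coverage class was 8.01 points. Over exons lower after knockdown the difference kept its sign in that class but was smaller. The class sets a floor on depth and does not equalise it between groups. The amount of PTBP1 RNA does not order the groups either: exon-excluded libraries had 2.96 times the control reads and 0.849 of the full-length reads, yet over exons chosen without 1 control library their mean PSI lay 4.54 and 4.99 points above the library left out (pooled SD 0.846), on the knockdown side, and −6.78 and −7.18 for exons lower after knockdown. Control cells had no siRNA against PTBP2, so a joint effect of PTBP1 RNA and that siRNA stays open. The siRNA was the same for both forms, but PTBP2 reads were not. At 1 site pair they were 10.67 ± 0.0566 RPM with full-length and 17.65 ± 1.43 with exon-excluded PTBP1. At the other they were 16.73 ± 0.537 and 26.11 ± 0.806. A part of PTBP2 RNA in the difference between the forms was not tested. The amount of protein was not measured and stays open. A weaker activity of the short form at many exons is a hypothesis that these values may fit.

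The second pattern is that microexons called after knockdown mostly rose. The table lists some microexons separately, but those of 27 nt or less in its ordinary exon types also rose, 51 of 60 against 40.5% of longer exons (Fisher exact odds ratio 8.32, p 6.52e-12). Control libraries were shallower, but in the deepest coverage class 42 of 53 rose against 31.7% (odds ratio 8.22, p 5.99e-12). A stronger repression of very short exons by PTBP1 or PTBP2 is a hypothesis that was not tested. How PSI was computed for them is not stated and stays open. Microexons and longer exons were not matched on their PSI in control, so a difference in room to rise or fall also stays open.

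The third pattern is that more DT40 events followed the number of deleted alleles than chance gives, though none was called. A trend had p under 0.05 for 764 events. Of the 45 orders of the 6 libraries 1, the real one, gave as many, and the highest other gave 694, so a random order of libraries is argued against. The 10 calls in the deepest class do not come from the smaller number of events tested, since the p-values of all events adjusted over that class alone gave 0 calls, while the median standard error was 1.51 in the fit of that class and 1.81 in the fit of all events. Small effects of the exon at its own locus may underlie the trend, and other differences between the cells of each genotype stay open.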

How the results depend on the processing

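Alternatives on first sites, list members, balanced reads, the deepest coverage class and comparisons with control were chosen after seeing the data; the other settings were planned. No called named event and no mean difference changed sign, while the balance of higher and lower calls turned in some settings. Of the settings tried for the main results 130 left the value within its bounds and 43 did not, for event types 65 and 15, for gene lists 161 and 22. For named events and the comparisons with control 2040 were unchanged in call, 142 lost it, 1 gained it and 30 counts moved. All lost calls of named events but 1 (SYNRG on the logit scale) were in the direct comparison of the PTBP1 forms.

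For knockdown against control the count of 1759 became 998 with the compared groups alone, where fewer libraries estimate the spread, 1021 with balanced exon reads and 1111 in the deepest coverage class, where fewer events are tested, 1156 to 1326 without a library of its arms, and 1568 to 1623 without another, where fewer libraries estimate the spread. Calls were mostly lower (44.4% higher), and more so with balanced exon reads and in the deepest class, where 35.4% were higher in each. Without a coverage filter 56.9% were higher and with the compared groups alone 54.9%. The balance also turned upward without either control library and without the unnumbered knockdown library. The cause of these shifts was not tested. With balanced reads or in the deepest class full-length PTBP1 against knockdown had more higher than lower calls (695 and 637, 699 and 649), as did exon-excluded PTBP1 with balanced reads (396 and 388). Full-length PTBP1 against knockdown gave 1332 with balanced reads and 1348 in the deepest class, and exon-excluded PTBP1 gave 784 and 927, for the same reasons, 781 to 972 without a library of its arms and 1223 to 1269 without another. The lone library of an arm was assumed to vary like the other groups.

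Exon-excluded against full-length PTBP1 was the least stable. The count of 158 became 58 on the logit scale (51 shared), 80 without a filter on mean PSI, 261 without trend and robust, 266 in the deepest class and 391 with no test; the cause was not tested. Of 141 calls without a coverage filter 21 were shared, and the balance of 96 higher and 62 lower became 59 and 82 there and 25 and 35 with the block. The count was 1 with the compared groups alone, where fewer libraries estimate the spread, and 8 to 81 without 1 library. The fits without 1 library all keep the same number of libraries, so that number does not explain the range among them. The count depended on which group lost a library, also for groups outside this comparison, and the cause was not tested. With the replicate number as a block it was 60 (59 shared); the cause was not tested, and libraries of equal number correlated at −0.011 to 0.025.

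In DT40 the 0 calls became 53, 33 and 36 (homozygous and heterozygous against wildtype, homozygous against heterozygous) without a coverage filter and 62, 36 and 42 with no test; the cause was not tested. The first became 10 in the deepest class, not through fewer events tested (0 by that alone). The overlap of genes between lines became 3 in the deepest class, where DT40 calls exist.

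The difference between PTBP1 forms over exons higher after knockdown, 7.28, was 8.52 for exons chosen at 15 points, 7.90 between library medians, 9.99 with balanced reads and 8.01 in the deepest class, and 6.68 to 7.87 without 1 library. The median difference per exon was smaller, 4.545 points. Over exons lower it was −5.26 and became −6.89, −5.89 between library medians, −4.57 in the deepest class and −7.04 to −4.87 without 1 library; the cause was not tested. The median difference per exon was −3.71 points.

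The planned quasi-binomial model was not run because the tables hold no inclusion and exclusion reads of exons. Simulated changes of 15 points were recovered 14 times in 100 in 293 and 7 in 100 in DT40 cells. Depth, the number of libraries and the number of changed events were not varied there.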

Other observations

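The test of matched chicken exons and the comparisons with control were chosen only after the result was seen. Exons released by the knockdown kept the reading frame more often than those lost: 62.0% of 716 against 48.1% of 941 had a length divisible by 3 (Fisher exact odds ratio 1.76, p 2.37e-08), beside 38.9% of exons that were not called. Of the 85 microexons that rose 88.2% did, and of the 631 longer exons that rose 58.5%. The share among microexons that fell or were not called was not counted, so the 88.2% cannot be tied to the rise. The tendency to rise went beyond microexons, since 102 of 159 called exons of 28 to 51 nt rose against 529 of 1398 longer ones (odds ratio 2.94, p 2.62e-10).

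In the fit of all libraries full-length PTBP1 also went past control. Against control it changed 234 events, 54 higher and 180 lower, of which 49 lay beyond control as seen from the knockdown, 40 on the knockdown side and 145 were not called in the knockdown. Exon-excluded PTBP1 changed 179, of which 125 lay on the knockdown side and 2 beyond. The comparisons with control and the knockdown comparison use the same control libraries, whose spread favours the knockdown side for both forms. The SUCO exon went from 93.9 ± 2.77% in control to 53.5 ± 3.44% with full-length PTBP1, and stood at 93.4% with exon-excluded PTBP1. LRCH3 went from 74.3 to 35.1% and the ataxin gene ATXN2 from 87.5 to 54.2%, while WASF3, an actin regulator, went from 14.6 to 39.5% and DST, a cytoskeletal linker, from 12.1 to 38.1%. These counts rest on the full set of libraries and on the settings. With the compared groups alone 0 events were called for either form, with the replicate number as a block 11 and 1, without a filter on mean PSI 69 and 60 and on the logit scale 81 and 177, while the deepest coverage class gave 390 and 364. Without any 1 of the 8 libraries 0 to 22 events were called for full-length and 1 to 5 for exon-excluded PTBP1. Without a coverage filter full-length PTBP1 gave 112 higher and 75 lower calls, of which 23 were shared.

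Matched chicken exons were followed over the deleted alleles. The mean PSI of matched exons whose human partner rose after knockdown, minus that of those whose partner fell, was −27.2 and −26.0 in wildtype, −25.0 and −26.3 in heterozygous and −23.5 and −24.0 in homozygous cells. The exact permutation p of the trend was 0.044 over 90 orders, of which the smallest possible is 0.022. Deleting the exon in chicken may therefore shift exons matched by symbol and length slightly toward the state seen after the human knockdown. The test came after the values, and a few exons may carry much of a mean. Median differences between homozygous and wildtype cells were 0.68 and −0.78 points, beside means of 1.83 and −1.04. The median of matched exons not called after knockdown was 0.245.

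Other DT40 exons followed the deleted alleles without passing the limma test. Of 11234 events 328 (2.92%; 179 upwards, 149 downwards) were ordered by deleted alleles in all 6 libraries, where chance gives 250 (2.22%), and the smallest adjusted p of the trend was 0.32. Among them were MAPKBP1 (66.9, 82.8 and 92.2% in wildtype, heterozygous and homozygous cells), the kinase gene WNK1 (59.8, 69.3 and 80.1%), the lipid transfer gene OSBPL9 (79.9, 71.6 and 55.2%) and PACSIN2 (52.9, 44.6 and 39.9%).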
